A study of Triticum aestivum with 20 samples.

How the data were processed

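Leaf RNA of bread wheat (Triticum aestivum), a hexaploid with A, B and D subgenomes, was measured in 20 libraries. The labels cross earthworms (present or absent) with water (kept watered or left to dry) in 5 accessions: the Watkins landraces YoGI_178, YoGI_203 and YoGI_287, the cultivar Shamrock (YoGI_349) and the commercial cultivar Skyfall. One protocol text calls YoGI_349 a landrace, while its genotype label says Shamrock. Per the labels' protocols, 2 plants shared a pot, RNA came from a leaf of each plant, and 4 biological replicates were pooled in equal amounts into 1 library for each accession and treatment. The same labels also give 4 plants per treatment, so the number of plants and pots behind a library is not clear. The replicate of the drought and earthworm comparisons is therefore the accession, numbered 1 (YoGI_178), 2 (YoGI_203), 3 (YoGI_287), 4 (YoGI_349) and 5 (Skyfall). In comparisons between accessions, the treatment libraries of an accession stand in as its replicates. Variation between the pooled plants of an accession could not be measured.

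The deposited table holds whole-number counts for 120744 gene identifiers. Per the submitters' processing notes, reads were aligned with HISAT2 (version 2.0.5m) and counted with featureCounts (version 1.5.0-p3). The genome build, the annotation and the strand setting of the counting are not given in the sources used here. The identifiers comprise 105200 genes placed on a chromosome, 2691 unplaced genes and 12853 identifiers of noncoding RNA form, and 38269 of all identifiers had 0 counts in every library. Homoeologous copies on the 3 subgenomes are close in sequence, and reads shared between copies can be lost or split by the counting, so the value of a single copy is uncertain to that extent. Total counts per library ran from 36.1 to 46.5, in units of 1e6. At that depth the median standard error of a log2 fold change was 0.17 for the averaged contrasts over all 20 libraries, 0.25 for contrasts of 5 against 5 and 0.35 for the interaction.

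None of the identifiers matched the reference table of 155467 genes, which names the genes of another annotation. The files do not pair identifiers with names. Gene lists of drought, defence, nutrient and development functions had been fixed before the data were examined, and none of them could be tested. Named genes are identifiers only, at most 2 that rose and 2 that fell per comparison. For drought they are the largest changes among genes with adjusted p under 0.05, mean log2 CPM of at least 0 and one direction in every accession pair (a pair with 0 counts on both sides has none). For the accession comparisons, and for comparisons with no called gene, they are the genes with the lowest p. The subgenome and the chromosome were read from the letters of the identifier, in place of the annotation that had been planned. The number in an identifier was used as the order of genes along a chromosome, by the naming convention of these identifiers. It is not a coordinate.

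Counts were tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, R 4.3.3). Genes were kept by edgeR's expression filter (a count of about 10 in at least 5 libraries and a total of at least 15), which left 58617 genes. The main model had the 4 treatment groups and the accession as a block, with 12 residual degrees of freedom. Accession-by-drought and accession-by-earthworm terms were tested by F tests in models with 9 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg within each comparison, and a gene was called at adjusted p under 0.05. Standard errors are the log2 fold change divided by the square root of F. CPM values are the deposited counts scaled to a library total of 1e6, with TMM-scaled library sizes for named genes, and with total counts for checks of libraries.

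The accession pairs the libraries, since the same line was grown in each treatment. In deviations from the treatment means, the 30 same-accession pairs correlated at 0.292 or more, and 20 of 20 libraries correlated best with their own accession. No pair of libraries agreed within sampling noise: the smallest chi-square per degree of freedom among 190 pairs was 19.1. Exact paired sign-flip tests, two-sided, were used for values per library. An exact test over 5 pairs cannot give a p below 0.0625. For drought, earthworms and their interaction, p-values measure the spread between accessions, each with 1 pooled library per treatment. The main fit pools that spread over the 4 treatment groups, with 12 residual degrees of freedom from 5 accessions. Each accession enters the averaged contrasts 2 times, so their edgeR p-values may be too small. For the accession test, the 4 treatment libraries of an accession stood in as its replicates. For accession by drought, its libraries with and without earthworms stood in as 2 replicates per water state. For accession by earthworms, its watered and drought libraries did so per earthworm state.

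The fits were tested on simulated data, with 200 genes changed by known folds. For drought averaged over earthworms, 59% of 2-fold and 80% of 4-fold changes were recovered, none in the wrong direction, and 8 unchanged genes were called. The shares were 56% and 88% for earthworms averaged over water, 37% and 70% for earthworms in watered pots, 28% and 67% for earthworms under drought, and 12% and 55% for the interaction. In the real data drought called 23240 genes, many more than the 200 changed here. Its adjusted threshold was therefore less strict, and the simulated drought shares do not carry over to it.

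The tests, the filter, the block, the rule for named genes and most alternatives were chosen before the data were examined. The alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma voom (limma 3.58.1), no filter and a stricter filter (50 counts in 5 libraries), no block, only the groups compared, a fold threshold of 2, and leaving out each accession and each library. Chosen after the data had been seen were scaling by library size alone, leaving out the 2 watered YoGI_178 libraries, and leaving out those 2 with 6 others: the 4 YoGI_203 libraries, the YoGI_287 library watered without earthworms and the YoGI_349 library under drought without earthworms. The values per library, the drought index, presence and absence of genes, windows along chromosomes, neighbouring genes and the subgenome shares of accession calls were also chosen after the data had been seen. Python 3 with numpy, pandas and SciPy was used for these.

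The drought index of a library is the mean log2 CPM of genes that rose under drought minus that of genes that fell, with the genes chosen in the other 4 accessions. A gene was missing from an accession when its mean CPM was under 0.1 of the median of the other accessions, all of them above 0.5 CPM. Windows held 40 such expressed genes, and 1000 shuffles of the missing genes gave the chance level. A gene was lacking in a library when its CPM was under 2% of the median of the other accessions under the same treatment, with more than 0.5 CPM in every library of those accessions. Intervals and floors (3 counts) cover counting error only, since reads amplified by PCR are not independent molecules. The confidence level is 95%.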

Results

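Leaf RNA was sequenced from 20 pooled libraries of 5 wheat accessions, each grown with and without earthworms and with and without drought. Every one of the 4 treatment groups held 5 libraries, 1 per accession. Pots in the drought groups received no water after day 38, and leaves were taken on day 53. Pots with earthworms held 3 animals (0.59 ± 0.07 g per pot). They were Allolobophora chlorotica, an endogeic species that lives and feeds in the soil. Mean total counts, in units of 1e6, were 41.6 ± 1.56 in watered pots without earthworms, 39.2 ± 3.37 in watered pots with them, 40.3 ± 4.70 under drought without them and 41.5 ± 2.56 under drought with them (SD, n = 5). Drought and water separated along the leading principal component, which held 27.1% of the variance. Presence and absence of 493 genes put 20 of 20 libraries nearer to all libraries of their own accession than to any other.

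The first question was how leaves of plants left without water differ from those of watered plants. Drought changed 23240 of 58617 tested genes, averaged over pots with and without earthworms: 11431 rose and 11809 fell. Each accession enters this test 2 times, so the count may be too high. The median log2 fold change was 0.74 among the genes that rose and -0.77 among those that fell. Changes of at least 2-fold numbered 4191 upward and 4145 downward, and changes of at least 8-fold 1043 upward and 276 downward. Genes that rose went from a median of 4.25 CPM in watered leaves to 7.76 under drought, and 95 of them had no count in any watered library. Genes that fell went from a median of 12.4 to 7.42 CPM, and the genes with no call stood at 3.20 and 3.18 CPM. In 4961 genes all 10 drought-watered pairs went up and in 5025 all went down, together 17% of the tested genes. Chance gives 0.195% if the 10 pairs are independent, but each accession enters them 2 times.

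TraesCS3A02G506000 had 0 counts in the 10 watered libraries and 17.8 ± 8.60 CPM under drought (SD, n = 10), at least 2226-fold higher against a floor of 3 counts over the watered group. TraesCS7A02G333100 had 1 count in the watered libraries and 29.4 ± 27.1 CPM under drought, a ratio of 10887 (95% exact binomial interval 1954 to 430048). Among genes that fell, TraesCS5D02G276300 went from 13.3 ± 12.8 to 0.496 ± 1.40 CPM, a log2 fold change of -6.12 ± 0.84 (SE; edgeR adjusted p = 5.53e-05). TraesCS2B02G041300 went from 29.8 ± 43.8 to 0.40 ± 1.02 CPM, a log2 fold change of -6.46 ± 0.94 (SE; edgeR adjusted p = 9.19e-05). Its watered level ran from 0.0242 to 110 CPM between libraries, Skyfall had 2 counts of it over its 4 libraries, and YoGI_178 with earthworms had 1 count in watered pots and 1 under drought.

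Drought calls were spread over the 3 subgenomes in nearly equal shares. Genes that fell made up 20.4% of tested A genes, 19.5% of B genes and 21% of D genes. The B share was lower than elsewhere (odds ratio 0.926, Fisher's exact test, adjusted p = 0.00292 over 6 tests) and the D share higher (odds ratio 1.07, adjusted p = 0.0101). Fisher's test takes genes as independent, but neighbouring genes were called together more often than by chance, so its p-values may be too small. Among genes changed at least 2-fold the B result no longer passed (odds ratio 0.948, adjusted p = 0.260) and the D result did (odds ratio 1.11, adjusted p = 0.0147). For genes that rose the shares were 19.4%, 19.4% and 20.1%, and none of the 3 passed the test. The part of all counts from A genes fell from 33.6% to 33.2%, and that from D genes rose from 34.1% to 34.4% (exact sign-flip test over 10 pairs, adjusted p = 0.0201 for D). Each accession enters those pairs 2 times, and within either earthworm treatment the exact sign-flip p for D was 0.125. Of 383 noncoding RNA identifiers tested, 15 rose and 3 fell.

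Drought libraries were less dominated by a few genes. The 10 most abundant genes of a library took 4.35 ± 0.66% of its counts in watered leaves and 2.42 ± 0.55% under drought (SD, n = 10), lower in 10 of 10 pairs (exact p = 0.00195, the smallest 10 pairs allow). The number of genes with at least 10 counts rose from 52907 to 54691, higher in 10 of 10 pairs (exact p = 0.00195). Each accession enters those pairs 2 times, with and without earthworms. The balance of rising and falling genes depends on the scaling. Scaled by library size alone, drought changed 27323 genes, 19761 upward and 7562 downward, and the median of all genes moved from 0.01 to 0.23 on the log2 scale.

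Without earthworms drought changed 13412 genes (6594 upward, 6818 downward), and with earthworms 14774 (7389 upward, 7385 downward). With only the groups compared in the fit, the counts were 9935 and 11129. The lists shared 4502 rising genes, where independent lists would share 831, and 4515 falling genes, where they would share 859. Of the genes called in both lists, 2 had opposite directions, and of the 19167 called in either list 96.5% had the same sign in both. Across genes, which are not independent replicates, the log2 fold changes correlated at Pearson's r = 0.834 and Spearman's rho = 0.729. Scaled by library size alone, 79.4% of the calls without earthworms and 68.1% of those with earthworms were upward. Without earthworms the count was 5751 when YoGI_178 was left out, 8715 without YoGI_203 and 7945 without Skyfall. It was 8529 without the YoGI_178 drought library, 8844 without both watered YoGI_178 libraries and 5233 without the 8 doubted libraries. With earthworms it was 9628 without YoGI_178 and 9285 without Skyfall.

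**Figure D1:**
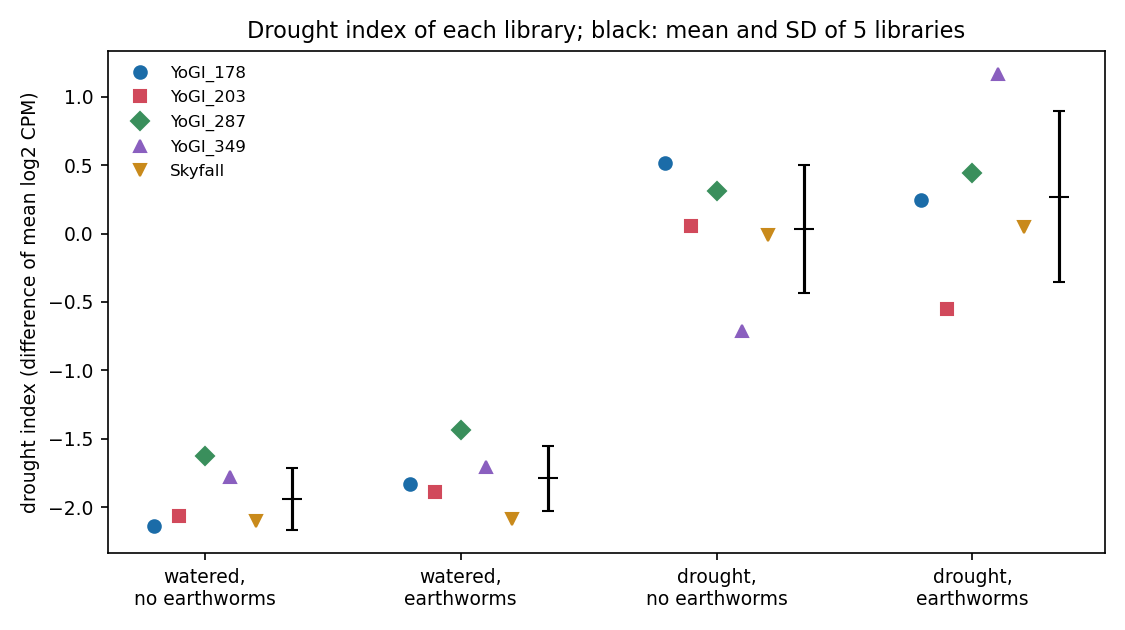
Drought index of each library (vertical axis, difference of mean log2 CPM between genes that rose and genes that fell in the other accessions) by treatment group, with the mean and SD of 5 libraries in black. Watered libraries lie between -2.14 and -1.44, and YoGI_349 under drought has both the lowest value (-0.71, without earthworms) and the highest (1.17, with earthworms).

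The strength of the drought response varied between libraries, and its difference between the earthworm treatments went both ways across accessions. The drought index was -1.94 ± 0.23 in watered pots without earthworms, -1.79 ± 0.24 with them, 0.03 ± 0.47 under drought without earthworms and 0.27 ± 0.62 with them (SD, n = 5). In YoGI_349 the index rose by 1.07 without earthworms and by 2.87 with them. In YoGI_203 it rose by 2.12 without and by 1.34 with earthworms. Averaged over accessions, the response with earthworms minus that without was 0.08 ± 1.02 (SD, n = 5; exact sign-flip p = 0.938).

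The second question was whether earthworms change leaf expression. No gene passed the edgeR test for earthworms averaged over water, in watered pots or under drought, and unadjusted p was under 0.05 for 3412, 2931 and 3452 of 58617 genes. DESeq2 called 27, 2 and 21 genes in these comparisons, and limma voom called 1, 0 and 0. Without the 8 doubted libraries edgeR called 1, 0 and 1 genes. The earthworm effects in watered and in drought pots correlated weakly across genes (Pearson's r = 0.157, Spearman's rho = 0.0824). Of the 9 library measures tested for earthworms, the share of counts from A genes passed: it was 33.3% with and 33.5% without earthworms, lower in 8 of 10 pairs (exact sign-flip p = 0.0215, adjusted p = 0.0483 over 18 tests). The difference averaged -0.142 ± 0.229 percentage points (SD), and each of the 5 accessions enters 2 times. Under drought the share was lower in 5 of 5 pairs (exact p = 0.0625, the smallest 5 pairs allow), and in watered pots it was lower in 3 of 5, by -0.0588 on average (exact p = 0.438).

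TraesCS7D02G161200 had the lowest p under drought and was also the lowest for earthworms averaged over water. It stood at 0.524 ± 0.318 CPM under drought without earthworms and at 11.1 ± 11.7 CPM with them (SD, n = 5), a log2 fold change of 4.05 ± 0.58 (SE; edgeR adjusted p = 0.172). In watered pots it stood at 10.8 ± 7.49 CPM without and 23.8 ± 18.6 CPM with earthworms. It was higher with earthworms in 10 of 10 pairs, among which the accessions recur. It was chosen for its low p over these same pairs, so their shared direction is no separate evidence of an earthworm effect. It remains a gene that did not pass the edgeR test on all libraries. DESeq2 called it under drought (adjusted p = 5.19e-11), and so did edgeR without the YoGI_178 library under drought with earthworms (adjusted p = 0.0316), without the Skyfall library under drought without earthworms (adjusted p = 0.0202), without both watered YoGI_178 libraries (adjusted p = 0.0443) and without the 8 doubted libraries (adjusted p = 0.00512). Over all its alternatives the adjusted p ran from 5.19e-11 to 1.0. Under drought, TraesCS5D02G163200 stood at 1.31 ± 0.332 CPM without and 0.419 ± 0.204 CPM with earthworms (edgeR adjusted p = 0.825; DESeq2 adjusted p = 0.00456), and TraesCS4A02G345700 at 0.396 ± 0.637 and 0.00422 ± 0.00943 CPM, the latter from 1 count (edgeR adjusted p = 0.825).

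In watered pots, TraesCS4A02G245400 stood at 0.0114 ± 0.0255 CPM without and 0.279 ± 0.0851 CPM with earthworms, and TraesCS3B02G171700 at 0.0109 ± 0.0151 and 0.194 ± 0.158 CPM. TraesCS4B02G192600 stood at 1.77 ± 0.496 and 0.879 ± 0.340 CPM, and TraesCS2D02G476900 at 1.41 ± 1.63 and 0.0101 ± 0.0226 CPM (SD, n = 5). The edgeR adjusted p of each of the 4 was 0.897. DESeq2 called TraesCS2D02G476900 (adjusted p = 0.0382).

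**Figure D2:**
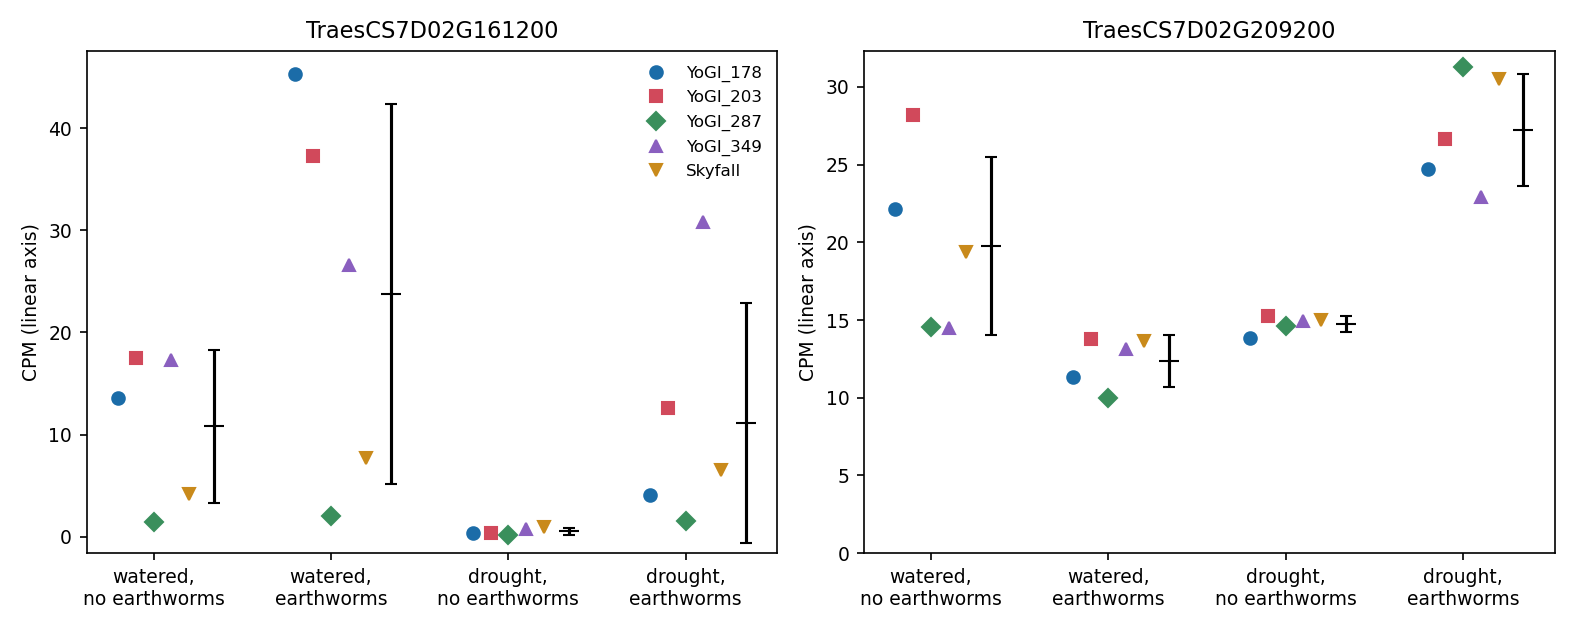
CPM (vertical axes, linear) of TraesCS7D02G161200 and TraesCS7D02G209200 in each library by treatment group, with the mean and SD of 5 libraries in black. Under drought without earthworms TraesCS7D02G161200 has a mean of 0.524 CPM and TraesCS7D02G209200 a mean of 14.7 CPM, below the 11.1 and 27.2 CPM with earthworms.

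The third question was whether earthworms alter the response to drought. The interaction called 0 genes with edgeR (unadjusted p under 0.05 for 3136), 0 with limma voom and 3 with DESeq2. The lowest p belonged to TraesCS7D02G209200, which stood at 19.8 ± 5.74 CPM in watered pots without earthworms, 12.4 ± 1.66 CPM in watered pots with them, 14.7 ± 0.537 CPM under drought without them and 27.2 ± 3.60 CPM under drought with them (SD, n = 5). Its interaction was 1.54 ± 0.21 on the log2 scale (SE; edgeR adjusted p = 0.134; DESeq2 adjusted p = 7.29e-07). TraesCS3A02G277300 was at 5.07 ± 0.916 CPM in watered pots and 1.95 ± 0.458 CPM under drought without earthworms, and at 4.15 ± 1.18 and 3.74 ± 1.18 CPM with them (edgeR adjusted p = 0.897; DESeq2 adjusted p = 0.0456). TraesCS5B02G557100 and TraesCSU02G032000 leaned the other way, with interactions of -0.95 ± 0.19 and -1.65 ± 0.34 on the log2 scale (SE; edgeR adjusted p = 0.897 for both).

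The fourth question was how the accessions differ. Expression differed between accessions for 11593 genes (19.8% of those tested), and 7162 without the 8 doubted libraries. Between pairs the count ran from 3775 (YoGI_287 against YoGI_203) to 7199 (YoGI_287 against Skyfall). TraesCS2B02G249100 was near absent from Skyfall (0.0948 ± 0.0411 CPM) and YoGI_349 (0.0856 ± 0.0235 CPM) and at 16.5 ± 2.48 CPM in YoGI_178 (SD, n = 4). TraesCS3B02G557200 had 0 counts in YoGI_287 and 19.9 ± 2.28 CPM in Skyfall. Without YoGI_287 its edgeR adjusted p was 0.172.

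Accession differences were least frequent on the D subgenome. They took in 14.8% of tested D genes, 21% of A genes and 23.2% of B genes (odds ratio for D 0.614, Fisher's exact test, 95% interval 0.586 to 0.644). That interval takes genes as independent and may be too narrow. The share of called genes was lowest on chromosome 4D, at 10%, and highest on chromosome 6B, at 28.6%. Among unplaced genes it was 37.9%.

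Genes missing from an accession lay together along some chromosomes. In Skyfall, 245 of 45138 expressed genes were missing, and the fullest window of 40 genes, on chromosome 7D, held 13 of them, where 1000 shuffles reached at most 5. That run went from identifier number 520100 to the last expressed gene of the chromosome, number 553500, and 21 of its 93 expressed genes were missing. In YoGI_349 the fullest window was on chromosome 2B, with 11 of 40 genes missing. Its run lay between numbers 562200 and 588100 and lacked 15 of 68 genes. The fullest windows of YoGI_287 (chromosome 7B) and YoGI_178 (chromosome 2A) held 9 and 7 missing genes, against at most 6 and 4 in shuffles. In YoGI_203 only 14 genes were missing, with at most 2 in a window. A gene at the level of the other accessions in 1 of the 4 libraries of an accession is not counted as missing. The YoGI_203 libraries differed from each other at 25 to 77 of the 493 presence and absence genes. Whether this lowered its count was not tested.

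**Figure D3:**
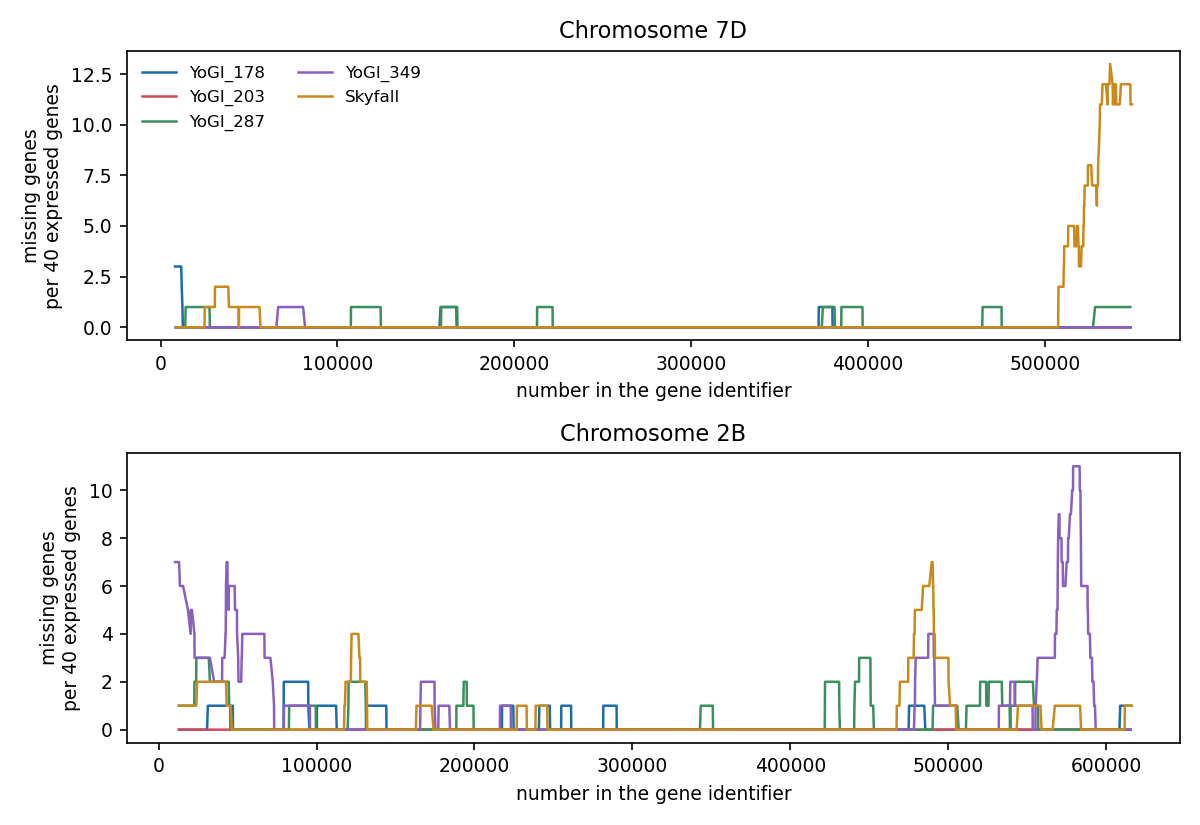
Missing genes per window of 40 expressed genes (vertical axes) along chromosomes 7D and 2B, ordered by the number in the gene identifier (horizontal axes), 1 line per accession. Skyfall reaches 13 at the end of chromosome 7D and YoGI_349 reaches 11 on chromosome 2B.

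The drought response differed between accessions for 17 genes. In 15 of them both drought libraries of YoGI_178 held under 5% of the level of the other accessions, while its watered libraries held more. TraesCS2D02G566500 was at 0 CPM in both drought libraries of YoGI_178 and at 1.69 and 2.23 CPM in its watered libraries, against means from 3.99 ± 0.485 CPM in Skyfall to 25.2 ± 2.31 CPM in YoGI_349 (SD, n = 4; edgeR adjusted p = 0.000684). TraesCS5B02G294500 was at 0 and 0.0690 CPM under drought and at 10.2 and 13.7 CPM in watered YoGI_178, against 64.6 ± 0.663 CPM in Skyfall (edgeR adjusted p = 0.000976). The count was 1047 with DESeq2, 0 with limma voom and 31 with no filter. It was 0 without YoGI_178, 3 without either drought library of YoGI_178, 10 without YoGI_287 and 5 without Skyfall. Leaving out 1 library with earthworms under drought gave 10 (YoGI_203), 9 (YoGI_287) and 9 (Skyfall). Leaving out 1 with earthworms in watered pots gave 42 (YoGI_178), 120 (YoGI_287), 9 (YoGI_349) and 10 (Skyfall). Without 1 library that had no earthworms it was 52 (YoGI_287), 40 (YoGI_349) and 9 (Skyfall) under drought, and 40 (YoGI_203) and 11 (YoGI_349) in watered pots.

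More widely, 74 genes were lacking in both drought libraries of YoGI_178 and present in all libraries of the other accessions. Their median level was 17.6% of the other accessions in the watered YoGI_178 library without earthworms and 6.34% in the one with earthworms. The median was 0% in the watered libraries of YoGI_287, YoGI_349 and Skyfall for the 82, 99 and 66 genes chosen in the same way. Both drought libraries of YoGI_178 differed at 0 of the 493 presence and absence genes, while the watered ones differed from them at 74 and 45. Drought libraries differed at 3 genes in YoGI_287, 11 in YoGI_349 and 3 in Skyfall. Watered libraries differed from drought libraries at 22 to 48, 22 to 33 and 19 to 24 genes there, so 45 is within the range of YoGI_287. The 4 libraries of YoGI_203 differed from each other at 25 to 77 of these genes.

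**Figure D4:**
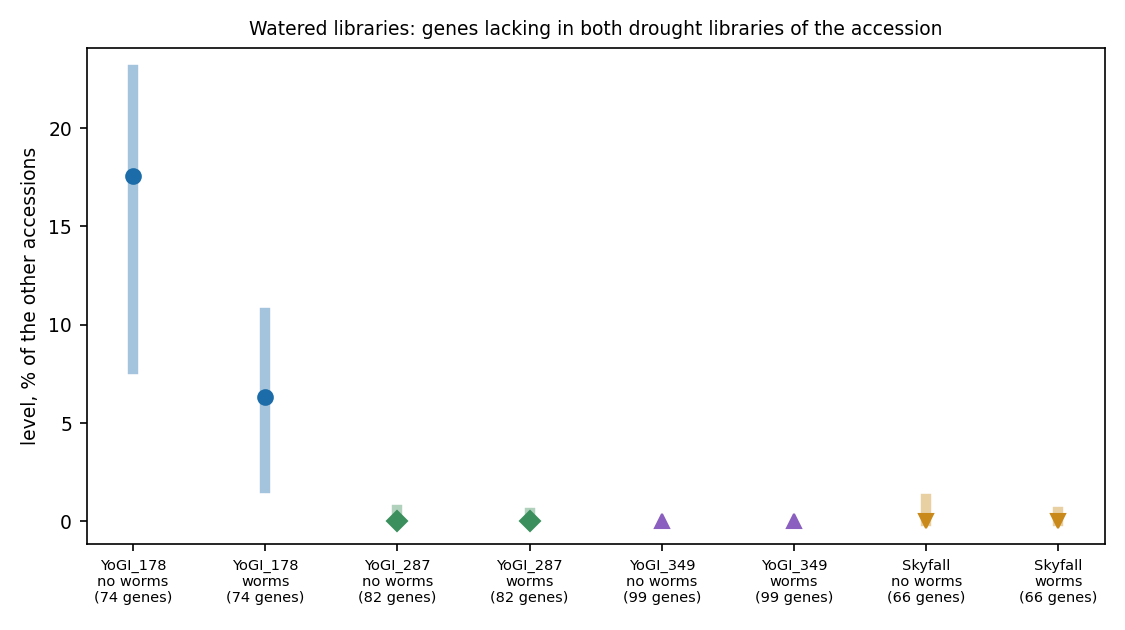
Level in each watered library, as a percentage of the other accessions (vertical axis), of the genes lacking in both drought libraries of the same accession, with medians as points and quartiles as bars. YoGI_203 is left out because it had 0 such genes, and the medians of YoGI_178 are 17.6% and 6.34% against 0% elsewhere.

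The test for an earthworm effect that differs between accessions called 13 genes, all of which rose under drought. Unadjusted p was under 0.05 for 1388 of 58617 genes (2.37%). Each of the 13 had 1 to 6 counts over all watered libraries together, so its effect rested on 1 drought library per accession and earthworm treatment. Watered libraries near 0 counts stood in as replicates, so these p-values do not measure spread between replicate drought pools. TraesCS6A02G295000 stood under drought at 5.41 CPM without and 59.0 CPM with earthworms in YoGI_349, and at 14.0 and 0.386 CPM in YoGI_203 (edgeR adjusted p = 0.000207). TraesCS3D02G237400 stood at 1.98 and 25.3 CPM in YoGI_349 and at 8.35 and 0.318 CPM in YoGI_203 (edgeR adjusted p = 0.00105). The count was 39 with DESeq2, 101 with limma voom, 3 without both watered YoGI_178 libraries and 0 without the 8 doubted libraries. It was 4 without YoGI_178, 0 without YoGI_203, 0 without either drought library of YoGI_203, 4 without the YoGI_349 library under drought with earthworms, 8 and 7 without the YoGI_178 library with earthworms under drought and in watered pots, and 8 without the Skyfall library under drought without earthworms.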

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

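The tests of explanations were chosen after the results were seen, except the test on genes with enough expected counts and that on the genes left in the runs, whose predictions were written before their results. The bootstrap interval of the former was added after its median was seen. Among 128 sets of 5 libraries, 24 held a library far from the other 4. In the 44 sets of library measures there were 5, where chance gives 2.2. The other sets are named genes, chosen from these data, so no chance rate applies to them.

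Drought responses differed between accessions for 17 genes, and 74 genes lacking in drought YoGI_178 leaves had reads in its watered libraries, at a median of 17.6% of the other accessions without earthworms. An equal mix of reads from the other 4 accessions would put genes present in 1 other accession only at about 4.39%. The median of 58 such genes was 0% (16 above 2%, 8 of them among the 20 of YoGI_203). Over the 27 with enough expected counts it was 0% (95% bootstrap interval 0 to 1.97, 8 above 2%). Reads from 1 accession alone would put its own genes near 17.6%. By accession the medians were 0% for Skyfall, YoGI_287 and YoGI_349 and 0.275% for YoGI_203. A smaller addition from YoGI_203 is not excluded. In the watered library with earthworms only 5 genes had enough counts (median 0.0986%, interval 0 to 14.0, where 1.58% would be needed), which decides nothing for that library. The 74 genes changed under drought by a median of 0.17 (quartiles -0.18 and 0.45, log2) in the other accessions. That argues against a fall shared by the accessions for these 74 genes. Genes absent there under drought had been left out by the selection, so it says nothing about those. Carried-in reads stay open for the library with earthworms. Plants of another genotype in the watered pools may account for the reads, and so may a drought response of YoGI_178 alone. These cannot be told apart with 1 pooled library per treatment.

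The test for an earthworm effect that differs between accessions called 13 genes, all of them higher under drought. With 1 to 6 counts each over all watered libraries, these 13 genes rested on 1 drought library per accession and earthworm treatment. Their mean log2 CPM correlated with the drought index over the 10 drought libraries (Pearson's r = 0.792, permutation p = 0.00534; Spearman's rho = 0.709, permutation p = 0.0278; r = 0.654 without the 2 farthest libraries), with permutations that ignore the 5 accession pairs. All 13 rose under drought, and the index is built from genes that rose, so a positive correlation can follow from their choice. Other rising genes were not set beside them, so the correlation decides nothing about the cause. In Skyfall the genes stood 1.22 to 4.76 higher with earthworms under drought (log2) while the index went only from -0.01 to 0.05. A swap of the YoGI_349 drought library without earthworms with a watered library is excluded, since the highest index of a watered library was -1.44 and none lay among the drought libraries. Drought responses of different strength in the pools of an accession may account for part of the calls, and so may an earthworm effect that differs between accessions, which cannot be told apart because each pool had 1 earthworm treatment.

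Missing genes lay together along chromosomes, with 13 in a window on chromosome 7D of Skyfall. Chance placement is excluded in Skyfall, YoGI_178, YoGI_287 and YoGI_349 (permutation p = 0.000999 in each, the smallest that 1000 shuffles can give), but not in YoGI_203 (permutation p = 0.153). One unbroken deletion of the run on chromosome 7D would leave nearly all its expressed genes missing, and 22.6% were. Reads from homoeologous copies could keep a deleted gene above the cutoff, so this argues against such a deletion without excluding it. Sequence that differs from the reference could lower the counts of the other genes too, and over the 464 genes of all runs that were not missing the median ratio to the other accessions was 0.831 (quartiles 0.481 and 1.08). That lies between the bounds set beforehand and decides nothing, and single runs lay on both sides, such as 0.310 (3D, YoGI_349), 0.679 (7D, Skyfall), 1.03 (7B, Skyfall) and 1.27 (3B, YoGI_349).

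The YoGI_287 library watered without earthworms had 50840 genes with at least 10 counts against 53035 to 53616 in its group, and 11% of its genes stood under 0.4 of the other accessions, against at most 2.46%. The top 10 genes took 1.87% of counts in YoGI_287 under drought with earthworms, against at least 2.27%, and 3.91% in YoGI_349 under drought without earthworms, against at most 2.52%. The TMM factor of the watered YoGI_178 library with earthworms was 1.01, against at most 0.947.

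Single genes stood apart in the following libraries, on the scale of log2(CPM + 0.5). TraesCS3B02G557200 was at -1.0 in each of the 4 YoGI_287 libraries. TraesCS5B02G294500 was at -1.0 and -0.81 in drought YoGI_178 with and without earthworms, and at 3.43 in watered YoGI_178 with earthworms. TraesCS2B02G041300 was at -0.49 and 1.92 in drought YoGI_349 with and without earthworms. TraesCS5D02G276300 was at 2.31 in drought YoGI_349 without earthworms. TraesCS4B02G192600 was at 1.66 in watered YoGI_203 without earthworms. TraesCS2D02G476900 was at 0.85 and -0.86 in Skyfall with earthworms under drought and in watered pots, and at -0.72 in YoGI_349 under drought without earthworms. The others rested on a few counts where the other 4 libraries had 0: TraesCS7A02G333100 at -0.93 in watered YoGI_178 without earthworms, TraesCS4A02G245400 at -0.84 in watered YoGI_203 without earthworms, TraesCS4A02G345700 at -0.94 in drought YoGI_287 with earthworms, TraesCS6A02G295000 at -0.92 in watered YoGI_349 with earthworms, and TraesCS3D02G237400 at -0.92 in watered YoGI_178 with earthworms.

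For accession the splits argue against there being no difference at all between accessions, as far as 40 splits allow. Shuffled accession labels put real accession differences into the residual spread, so the splits give no chance level for the size of the count. For drought the splits cannot exclude chance, since few of the others parted all accession pairs, and exact tests over 5 pairs cannot go below p = 0.0625. The other drought splits also had drought and watered libraries on both sides, so the drought effect entered their residual spread. In 40 splits of the libraries, the real one included, 1 gave as many genes: 23240 averaged (highest other 0), 13412 without earthworms (highest other 0), 14774 with earthworms (highest other 0) and 11593 for accession (highest other 1). Among the other splits, 5 without and 3 with earthworms parted all 5 pairs and called 0 genes, and 0 did so for all 10 pairs. For earthworms the real count is 0, which 40 of 40 splits reach by construction, so the splits decide nothing there. The highest other was 36 averaged, 12 in watered pots, 17 under drought and 1 for the interaction.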

How the results depend on the processing

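Scaling by library size alone and the settings that left out the YoGI_178 or doubted libraries were chosen after the data had been seen. The 3 drought counts and the accession count stayed within 1.5 times under the other scalings, DESeq2, limma voom, both filters and, for drought, the groups compared alone. Without the accession block (the pairing), drought called 18829 genes averaged, 9097 without and 10693 with earthworms, and all earthworm comparisons called 0, so the block changed no call by over 1.5 times. With a fold threshold of 2, drought called 8336 averaged, 6271 without and 7028 with earthworms, by construction fewer. At that threshold the odds ratio of falling B genes was 0.948 (adjusted p = 0.260, no longer passing) and that of A genes 0.949, on the other side of 1, neither passing. DESeq2 called 27 genes for earthworms averaged, 2 in watered pots, 21 under drought, 3 for the interaction, 1047 for accession by drought and 39 for accession by earthworms. limma voom called 1 for earthworms averaged, 0 for accession by drought and 101 for accession by earthworms. With no filter, accession by drought called 31. Without both watered YoGI_178 libraries, drought without earthworms called 8844, earthworms under drought 1 and accession by earthworms 3. Without the 8 doubted libraries these were 5233, 1 and 0, with 7162 for accession and 1 for earthworms averaged. The cause of these moves was not tested.

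Leaving out 1 accession or 1 library gave 17520 to 24311 for drought averaged, 5751 to 15397 without and 9285 to 17132 with earthworms, 8214 to 13401 for accession, 0 to 120 for accession by drought and 0 to 15 for accession by earthworms. It gave 0 to 1 for earthworms averaged, in watered pots and under drought, and 0 to 0 for the interaction. Averaged and under drought, 1 gene was called higher without YoGI_178 under drought with earthworms, and 1 higher without Skyfall under drought without earthworms. Averaged and in watered pots, 1 gene was called lower without YoGI_287 watered with earthworms. Named genes kept their side of the threshold in 730 combinations of gene and setting, lost the call in 20 and gained it in 10. Most of the 730 are earthworm and interaction genes that stayed above the threshold. Each named drought gene stayed called in its 35 settings and kept its direction. No direction reversed, but the accession F tests have none to score. Accession by drought could not be fitted without the watered YoGI_178 libraries. The gene list alternatives (fry, estimated correlation, no block, no filter) were not run, as no list could be built. In simulation 12% of 2-fold changes of the interaction were recovered, so a count of 0 there leaves room for changes of that size.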

Other observations

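All tests of this part were chosen after the data had been seen. Genes that moved together under drought were neighbours more often than chance. Of 57583 adjacent pairs of tested genes, in identifier order, 2712 were both higher under drought, where shuffling within chromosomes gave 2227 on average and at most 2333. Both lower were 2964 pairs, against 2377 on average and at most 2508, and opposite pairs numbered 4089, against at least 4400 in shuffles. The longest run of falling genes, on chromosome 1B between identifier numbers 434600 and 435900, held 10 genes, and the longest run of rising genes, on chromosome 3B between 62700 and 63500, held 8.

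Unplaced genes took a larger part of the counts under drought, 0.889 ± 0.112% against 0.689 ± 0.0326% in watered leaves (SD, n = 10), higher in 10 of 10 pairs (exact sign-flip p = 0.00195, adjusted 0.00586 over 18 tests). In watered pots the drought index was higher with earthworms in 5 of 5 accessions, by 0.15 ± 0.11 (SD, n = 5; exact sign-flip p = 0.0625, the smallest 5 pairs allow). Under drought it was higher in 3 of 5 (exact p = 0.812), and over all 10 pairs in 8 (exact p = 0.473).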
